A study of Tribolium castaneum with 9 samples.

How the data were processed

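The study sequenced RNA from adult red flour beetles of a susceptible phenotype (Tribolium castaneum, a pest of stored grain), with and without exposure to carbonyl sulfide (COS), a fumigant gas. There are 9 libraries in 3 groups of 3: the whole body of untreated beetles, Malpighian tubules of COS-treated beetles (the excretory organ of insects) and fat body of COS-treated beetles (the organ of storage and intermediary metabolism). Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase I, and reads were aligned to assembly Tcas5.2. Trimmomatic version 0.32 is named in the submitters' processing notes. The aligner and the counting program are not given in the sources used here, nor is any dose or time, and the meaning of the number in the titles of the fat body samples is not given either.

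The authors deposited a single table of 5467 genes. Per the file headers it holds an expected count per gene and library, and each deposited count is a whole number. It also holds, per the file headers, a normalized signal that the authors obtained with DESeq, FPKM and TPM values from the authors, and the authors' log2 fold change for 3 comparisons. Each listed gene had an absolute log2 fold change of at least 1 in at least 1 comparison of the authors' deposited table: 3284 genes for tubules over control, 3211 for fat body over control and 4289 for fat body over tubules in the authors' deposited table. The genes were thus chosen on these same samples, other genes are not analysed here, and counts of changed genes and of list members below are not independent evidence. Choosing genes on the contrast between the tissues also favours genes with opposite directions in them. The ratio of count to FPKM and gene length gave each library's total, and the ratio of count to normalized signal gave the authors' size factors. Gene names are those of the deposited annotation. Of the 5467 identifiers, 5099 matched a table of RefSeq genes of assembly icTriCast1.1, which was used for names only, so no coordinates are given. The other per-sample value columns numbered 0.

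The expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, with filterByExpr, TMM factors computed on the listed genes, the recovered totals as library sizes, all 9 libraries in 1 fit and no covariate. A gene passed the test at a Benjamini-Hochberg adjusted p under 0.05 over the 5358 genes tested, and 109 genes fell to the filter. Levels are TMM-scaled CPM over the library total, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. This SE is approximate: the absolute log2 fold change divided by the square root of the quasi-likelihood F. It may be too small for genes of few counts. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The 28 lists, written as text patterns before the data were examined, cover cytochrome P450, glutathione S-transferase, UDP-glucuronosyltransferase, esterase, ABC transporter, carbonic anhydrase, sulfide metabolism, cytochrome c oxidase, other respiratory chain, antioxidant, heat shock, glycolysis, tricarboxylic acid cycle, fatty acid oxidation, fatty acid and lipid synthesis, ribosomal protein, proteasome, immune and apoptosis genes, and markers of fat body, Malpighian tubule, muscle, cuticle, gut, nervous system, sensory organs, testis and ovary. Text matches that did not belong were corrected before any test, with 37 members removed and 7 added. The lists were also run as first written.

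The rule for named genes was fixed before the data were examined. It takes, per comparison, the 4 highest and 4 lowest log2 fold changes among genes that passed the test, whose groups did not overlap, whose mean was above the median and which had a known description. For each detoxification, respiration and stress list it takes the member with the largest rise and the one with the largest fall against control. For each other list it takes the most abundant member, and for both tissues together the 4 genes in each direction with the largest smaller change. Other genes are named only where the text says that they were chosen after their values were seen. Many named genes belong to families of close copies (cathepsin L, multidrug resistance-associated proteins, P450s, carboxylesterases), and since it is not given how shared reads were counted, the split of reads among such copies is uncertain.

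The test was checked on simulated counts with 200 changed genes per comparison and 5358 genes. For tubules over control it recovered 28% of 2-fold, 86% of 4-fold and 86% of 8-fold changes, with 7 false calls among 5158 unchanged genes. For fat body over control it recovered 16%, 84% and 94%, with 5 false calls, and for fat body over tubules 22%, 82% and 98%, with 3. Changes of 1.5-fold were recovered at 0%, 2% and 4% in the same order. In the real table the genes were selected for change, and 3366, 3704 and 4275 passed in the 3 comparisons. The simulated data held neither the selection nor so many changed genes, so these rates do not carry over to it. The acceptance limit for 8-fold changes was lowered to 75% after the first result was seen. Of 10 simulated lists shifted by 1.5 log2 units, 9 were recovered, with 0 of 40 unshifted lists called, on data without correlation between genes. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, at least 50 counts in 3 libraries, a fold threshold, fits of 2 groups, the replicate number as a block, and each library left out in turn. The authors' size factors, library totals alone, and the fit without control replicate 3 and fat body replicate 1 were added after the data were examined.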

Results

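RNA was measured in 3 libraries each of control whole body, COS Malpighian tubules and COS fat body. Library totals, recovered from the deposited values, were 13435869, 13898838 and 14803877 reads for the controls. They were 19866421, 15175796 and 15408298 reads for tubules and 16125682, 18174747 and 16225672 for fat body. The listed genes held 58.0% to 60.9% of the reads in controls, 45.7% to 50.5% in tubules and 67.0% to 67.3% in fat body. The labels do not say that replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Within groups, chi-square per degree of freedom between libraries ran from 21.7 to 147, so no pair agreed within sampling noise. All genes in the table had been selected on their fold changes in these samples, so counts of changed genes and list members are not independent evidence. Against the control, tissue and treatment changed together, so those contrasts measure both at once. Both tissues are labelled COS, but with no dose or time given, equal treatment of them was not tested.

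The groups separated on the first principal components. PC1 held 68.1% of the variance and parted tubules from fat body, and PC2 held 20.9% and parted the whole body from both. Control replicate 3 stood apart from the other controls (chi-square per degree of freedom 89.3 and 91.5), and fat body replicate 1 from the other fat body libraries (147 and 133, against 63.5 between those). Testis and sperm markers moved with them: the median member stood 1.68 log2 units above its mean over the 9 libraries in control replicate 3, against 0.35 and 0.25 in the other controls. It stood at 0.24 in fat body replicate 1, against -1.65 and -0.75. Outer dense fiber protein 2 (LOC662898), a sperm tail component, stood at 429, 442 and 1016 CPM in controls 1 to 3. Relative to TMM, the authors' size factors shifted log2 fold changes by -0.49 for tubules over control, 0.16 for fat body over control and 0.65 for fat body over tubules. Library totals alone shifted them by -0.23, -0.26 and -0.02. RLE factors shifted them by 0.04, 0.20 and 0.16, and upper-quartile factors by -0.22, -0.13 and 0.09.

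**Figure D1:**
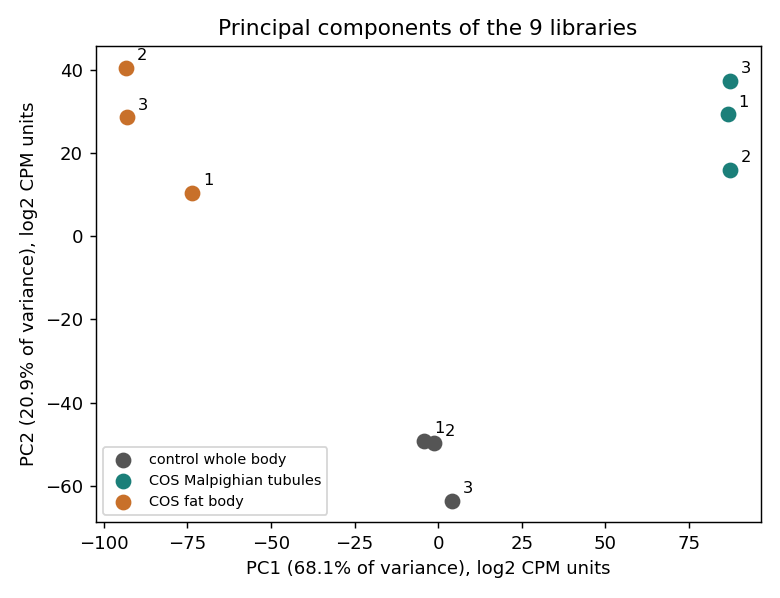
Principal components of log2 CPM for the 9 libraries, PC1 (68.1% of variance) across and PC2 (20.9%) up, in log2 CPM units, with a point per library, its replicate number and its group in colour. Tubules lie at the right, fat body at the left and the whole body at the bottom.

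In COS Malpighian tubules, cathepsin L1, zingipain-2, mucin-21 and cytochrome P450 6a14 stood far above the whole body. Camera called the muscle, nervous system, sensory and lipid synthesis lists lower, and none of these calls held with an estimated correlation (adjusted p from 0.207 to 0.487). Cathepsin L1 (LOC660551), a cysteine protease, rose from 1.45 ± 1.80 CPM to 1079 ± 332 CPM (log2 fold change 9.53 ± 1.04, adjusted p = 6.61e-05, edgeR). Zingipain-2 (LOC658343), another cysteine protease, changed by 8.19 ± 0.52, adjusted p = 4.94e-06, and mucin-21 (LOC107397713) by 6.46 ± 0.29, adjusted p = 1.72e-06. Cytochrome P450 6a14 (LOC658760), of an oxidative detoxification family, rose by 5.80 ± 0.31, adjusted p = 2.6e-06, reaching 717 ± 86.96 CPM from 12.9 ± 1.80 CPM. Among described genes with a mean above the median and groups that did not overlap, the lowest were chemosensory protein Csp13 (-7.51 ± 0.996, adjusted p = 0.000198) and ejaculatory bulb-specific protein 3 (LOC103313838, -7.48 ± 0.41, adjusted p = 2.94e-06). Within those limits they were followed by microtubule-associated protein 1B (LOC660329, -5.60 ± 0.59, adjusted p = 5.44e-05) and protein takeout-like (LOC103312153, -5.59 ± 0.40, adjusted p = 8.8e-06).

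Over all genes, 1747 rose and 1619 fell in tubules against control, 51.9% of the calls upward, and 1992 did not pass. With the authors' size factors the split was 1259 higher and 2417 lower, or 34.2% upward, with library totals alone 43.7%, with upper-quartile factors 44.2% and with RLE 53.0%. The groups did not overlap in 72.4% of the genes tested. Chance gives 10% only for genes not selected on these samples, so this share is no evidence.

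Detoxification genes went both ways in tubules. Among P450s 25 higher and 30 lower of 74 tested members passed, with cytochrome P450 4C1 (LOC662300, 5 counts over the tubule libraries) the lowest at -6.69 ± 0.50, adjusted p = 1.06e-05. Glutathione S-transferases, which conjugate electrophiles, had 3 higher and 5 lower of 11. They ranged from LOC657602 (4.32 ± 0.36, adjusted p = 1.61e-05, 264 ± 81.8 CPM against 13.2 ± 1.36 CPM) to LOC655751 (-2.10 ± 0.34, adjusted p = 0.00057). UDP-glucuronosyltransferases had 7 higher and 6 lower of 21, with LOC655958 at 2.79 ± 0.30, adjusted p = 5.79e-05 and LOC660846 at -2.41 ± 0.22, adjusted p = 2.49e-05. Esterases had 7 higher and 14 lower of 31, with venom carboxylesterase-6-like (LOC107399265) at 2.53 ± 0.54, adjusted p = 0.00302 and alpha-esterase like protein E1 (LOC661102) at -4.95 ± 0.34, adjusted p = 7.14e-06. ABC transporters, which export conjugates, had 24 higher and 13 lower of 51 (median 0.13; camera adjusted p = 0.00599, adjusted p = 0.424 with an estimated correlation). Their median was below 0 with upper-quartile factors (-0.094), the authors' size factors (-0.36) and library totals (-0.11). On ranks camera gave adjusted p = 0.103. The multidrug resistance-associated proteins LOC657021 (4.45 ± 0.40, adjusted p = 2.39e-05) and LOC658599 (-3.55 ± 0.43, adjusted p = 0.000122) were the extremes.

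Carbonic anhydrases, enzymes that also hydrolyse COS, had 1 higher and 4 lower of 7. Carbonic anhydrase 1 (LOC658563) rose by 1.98 ± 0.19, adjusted p = 3.14e-05. Beta carbonic anhydrase 1 (LOC659585) changed by -2.11 ± 0.21, adjusted p = 4.45e-05, from 105 ± 7.57 CPM to 24.3 ± 7.24 CPM. Both sulfide metabolism genes tested fell, among them cystathionine beta-synthase (LOC656954, -2.05 ± 0.22, adjusted p = 6.64e-05). Cytochrome c oxidase, the last complex of the respiratory chain, had 1 higher and 2 lower of 6. Subunit 6C (LOC656279) stood at 1.66 ± 0.21, adjusted p = 0.000159. Mitochondrially encoded subunit I (KEF75_p12) stood at -0.76 ± 0.18, adjusted p = 0.0044, from 56442 ± 6948 CPM to 33294 ± 6319.6 CPM. Other respiratory chain genes had 0 higher and 8 lower of 21, the lowest being NADH dehydrogenase subunit 1 (KEF75_p01, -1.34 ± 0.25, adjusted p = 0.00131). Antioxidant genes had 3 higher and 1 lower of 6, with peptide methionine sulfoxide reductase (LOC655619) at 2.42 ± 0.41, adjusted p = 0.000779 and peroxiredoxin-6 (LOC656825) at -1.999 ± 0.37, adjusted p = 0.00133. Heat shock genes had 6 higher and 4 lower of 13. Of the small heat shock proteins named lethal(2)essential for life, LOC664276 rose by 5.07 ± 0.71, adjusted p = 0.000279 and LOC657196 changed by -2.11 ± 0.16, adjusted p = 1.11e-05.

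Among metabolic lists in tubules, fatty acid and lipid synthesis had 8 higher and 34 lower of 46 (median -1.43; camera adjusted p = 0.000603, adjusted p = 0.424 with an estimated correlation). Fatty acid synthase (LOC662899) fell from 1879 ± 587 CPM to 179 ± 24.2 CPM (-3.39 ± 0.43, adjusted p = 0.000156). Glycolysis had 0 higher and 4 lower of 7, the tricarboxylic acid cycle 0 higher and 7 lower of 18, and fatty acid oxidation 2 higher and 6 lower of 13. Fructose-bisphosphate aldolase (LOC103313429) changed by -0.71 ± 0.13, adjusted p = 0.00139, mitochondrial aconitase (LOC663732) by -1.06 ± 0.19, adjusted p = 0.00106, and trifunctional enzyme alpha (LOC662336) had -0.15 ± 0.16, adjusted p = 0.448 (-0.63, adjusted p = 0.015, with the authors' size factors). Ribosomal protein genes had 2 higher and 0 lower of 5, and proteasome genes 2 higher and 0 lower of 3. The proteasome subunit LOC663555 (0.44 ± 0.16, adjusted p = 0.0365) no longer passed without control replicate 1 (0.39, adjusted p = 0.114) or 2 (0.39, adjusted p = 0.123). Nor did it pass without tubule replicate 1 (0.42, adjusted p = 0.0866) or 3 (0.40, adjusted p = 0.0951), or fat body replicate 2 (0.44, adjusted p = 0.0542). It also did not pass with DESeq2 (0.49, adjusted p = 0.0848), RLE (0.49, adjusted p = 0.0806), upper-quartile factors (0.23, adjusted p = 0.202) or library totals (0.22, adjusted p = 0.244). Its direction turned with the authors' size factors (-0.044, adjusted p = 0.808). Immune genes had 2 higher and 7 lower of 12, though lysozyme (Lyz) rose by 1.01 ± 0.21, adjusted p = 0.00218 (0.52, adjusted p = 0.0637, with the authors' size factors). Apoptosis genes had 5 higher and 0 lower of 7 (camera adjusted p = 0.0798, and 0.0391 on ranks), with the inhibitor of apoptosis LOC663941 at 1.96 ± 0.23, adjusted p = 0.000104.

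Tissue markers also differed in tubules. Malpighian tubule markers had 22 higher and 6 lower of 50 (median 0.29, -0.20 with the authors' size factors; camera adjusted p = 0.00312, adjusted p = 0.487 with an estimated correlation). The V-ATPase proteolipid LOC656327, part of the proton pump of tubules, rose from 374 ± 28.4 CPM to 1575 ± 237 CPM. Muscle markers had 3 higher and 30 lower of 38 (median -2.39; camera adjusted p = 2.34e-12, adjusted p = 0.421 with an estimated correlation). Nervous system markers had 2 higher and 29 lower of 40 (median -1.42; camera adjusted p = 0.00014, adjusted p = 0.487 with an estimated correlation). Sensory markers had 3 higher and 27 lower of 48 (median -1.91; camera adjusted p = 0.00014, adjusted p = 0.207 with an estimated correlation). Fat body markers had 2 higher and 11 lower of 15. Their camera adjusted p was 0.054, with 0.0292 on ranks, 0.0333 with RLE factors and 0.0129 without control replicate 3 and fat body replicate 1. Their most abundant member, vitellogenin (LOC660042), did not pass, at 405 ± 97.3 CPM in tubules against 540 ± 182 CPM in the whole body (-0.42 ± 0.32, adjusted p = 0.268, edgeR). Cuticle markers had 11 higher and 18 lower of 40, and testis 7 higher and 5 lower of 43. Gut digestive markers had 21 higher and 13 lower of 61. Aminopeptidase N-like LOC661831 stood at 1.21 ± 0.36, adjusted p = 0.0167. Its call was lost without control replicate 1 (1.03, adjusted p = 0.063), control replicate 2 (0.96, adjusted p = 0.0575) or tubule replicate 2 (0.92, adjusted p = 0.0662) and with the authors' size factors (0.75, adjusted p = 0.079). All 3 ovary and egg markers rose against the whole body, though 1 of them was higher in fat body than in tubules. Vitellogenin receptor (LOC657346), the yolk uptake receptor of oocytes, stood at 604, 202 and 857 CPM in the 3 tubule libraries against 57.2, 105 and 34.2 in controls (3.08 ± 0.79, adjusted p = 0.00784). Adjusted over the list alone, counts in this comparison were as given except for other respiratory chain (0 higher and 5 lower), glycolysis (0 higher and 3 lower), muscle (3 higher and 31 lower), gut digestive (21 higher and 12 lower) and testis and sperm (6 higher and 1 lower). Median and mean differed in sign for cytochrome c oxidase and heat shock. Median and test differed in direction for cytochrome c oxidase and heat shock. Medians changed sign with the scaling for ABC transporter (0.13, range -0.36 to 0.15), cytosolic ribosomal protein (0.076, range -0.41 to 0.11), proteasome (0.44, range -0.044 to 0.49) and Malpighian tubule (0.29, range -0.20 to 0.32).

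**Figure D2:**
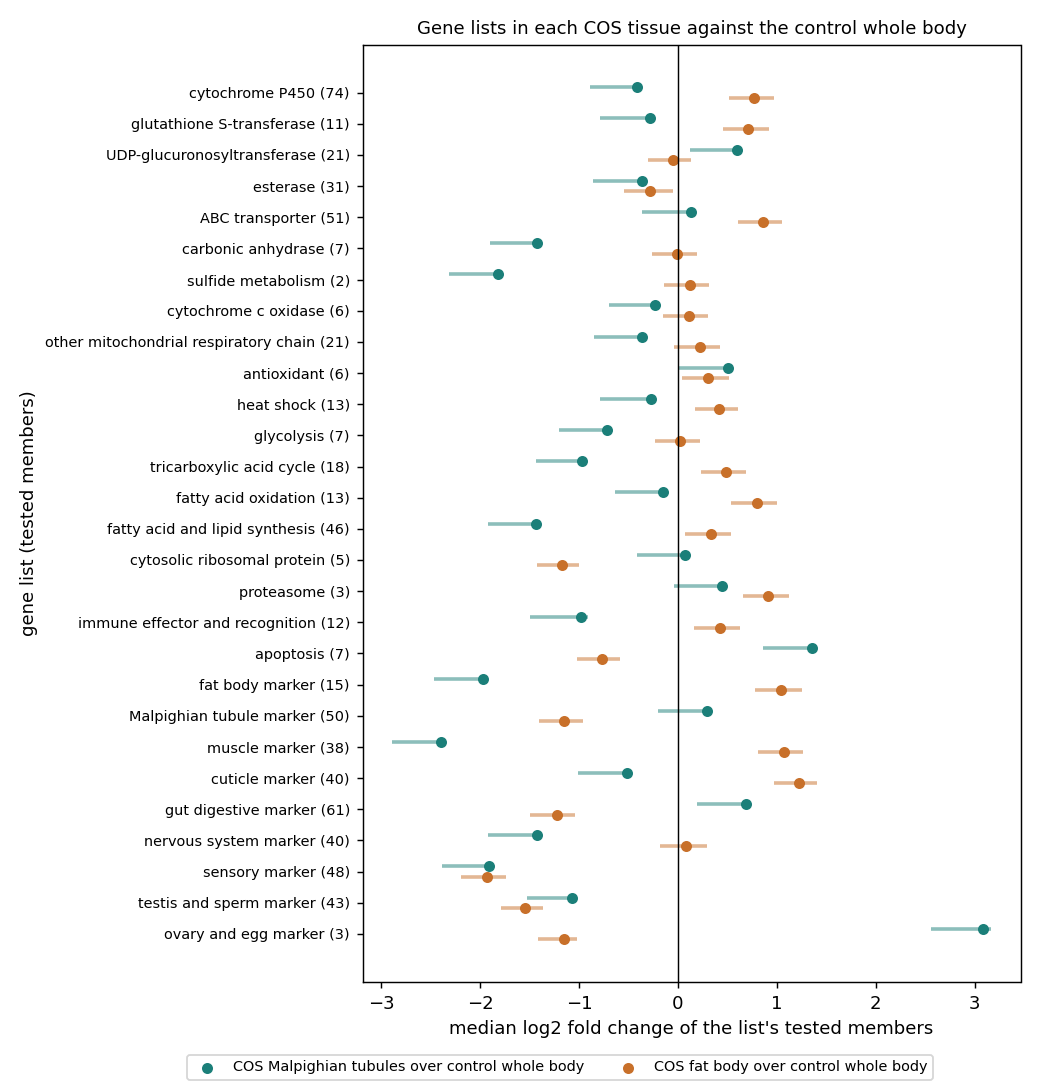
Median log2 fold change of each gene list's tested members (number in parentheses) over control whole body, in tubules and fat body. Points give TMM scaling and lines the range over 5 scalings. Muscle markers lie at -2.39 in tubules and 1.07 in fat body, and ABC transporters cross 0 in tubules.

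In COS fat body, camera called the P450, ABC transporter, fatty acid oxidation, cuticle and muscle lists higher than the whole body and the sensory and testis lists lower. None of these calls held with an estimated correlation (adjusted p from 0.504 to 0.954). Vitellogenin (LOC660042), the yolk precursor made by fat body, rose from 540.3 ± 182 CPM to 8602 ± 3085 CPM (3.99 ± 0.36, adjusted p = 7.31e-05, edgeR). Protein henna (LOC655392), phenylalanine hydroxylase, changed by 3.90 ± 0.25, adjusted p = 2.81e-05, P450 6k1 (LOC659136) by 3.89 ± 0.30, adjusted p = 4.42e-05 and P450 4C1 (LOC660270) by 3.84 ± 0.49, adjusted p = 0.000289. Within the limits on description, mean and overlap, the lowest were microtubule-associated protein 1B (LOC660329, -9.36 ± 0.73, adjusted p = 4.49e-05) and chymotrypsin-1 (LOC103313304, -8.71 ± 1.95, adjusted p = 0.00423). Within those limits they were followed by a troponin C (LOC659336, -8.01 ± 1.06, adjusted p = 0.000351) and ejaculatory bulb-specific protein 3 (LOC103313838, -7.79 ± 0.42, adjusted p = 2.4e-05). In all, 1726 genes rose and 1978 fell, 46.6% of the calls upward, and 1654 did not pass. With library totals alone the split was 1349 higher and 2399 lower (35.99% upward) and with upper-quartile factors 1514 higher and 2219 lower (40.6%). The majority turned upward with RLE, at 1869 higher and 1819 lower (50.7%), and with the authors' size factors, at 1916 higher and 1781 lower (51.8%). The groups did not overlap in 78.0% of the genes tested, a share that the selection of genes on these samples favours. The 10% that chance gives holds only for unselected genes.

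Detoxification genes in fat body also went both ways. P450s had 40 higher and 19 lower of 74 (median 0.77; camera adjusted p = 0.0138, adjusted p = 0.887 with an estimated correlation). The lowest was P450 6a20 (LOC658506, 4 counts over the fat body libraries) at -6.29 ± 1.07, adjusted p = 0.00112. ABC transporters had 28 higher and 10 lower of 51 (median 0.86; camera adjusted p = 0.0114, adjusted p = 0.852 with an estimated correlation). They ranged from the multidrug resistance-associated protein LOC656937 (3.41 ± 0.45, adjusted p = 0.000358) to LOC660481 (-3.12 ± 0.28, adjusted p = 7.44e-05). Glutathione S-transferases had 5 higher and 0 lower of 11, led by LOC659302 (1.73 ± 0.26, adjusted p = 0.000605, 532 ± 151 CPM against 161 ± 32.2 CPM). UDP-glucuronosyltransferases had 9 higher and 5 lower of 21, with LOC660739 at 2.73 ± 0.25, adjusted p = 8.2e-05 and LOC661391 at -2.01 ± 0.36, adjusted p = 0.00148. Esterases had 7 higher and 12 lower of 31, and the esterases FE4 LOC656282 and LOC661621 stood at 1.37 ± 0.28, adjusted p = 0.0027 and -6.69 ± 0.64, adjusted p = 9.37e-05.

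Carbonic anhydrases in fat body had 2 higher and 1 lower of 7. Carbonic anhydrase 1 (LOC658563) stood at 0.72 ± 0.18, adjusted p = 0.00767. It did not pass with library totals alone (0.46, adjusted p = 0.068) or without control replicate 3 and fat body replicate 1 (0.58, adjusted p = 0.0518). Carbonic anhydrase 14-like (LOC103315169) stood at -2.57 ± 0.82, adjusted p = 0.021, at -2.30, adjusted p = 0.0725 without fat body replicate 3 and at -4.01, adjusted p = 0.0017 without fat body replicate 1. Of the 2 sulfide metabolism genes neither passed. Cytochrome c oxidase had 2 higher and 1 lower of 6. Mitochondrially encoded subunit II (KEF75_p11) stood at 0.86 ± 0.18, adjusted p = 0.00314 and subunit 6C (LOC656279) at -1.26 ± 0.21, adjusted p = 0.000996. Other respiratory chain genes had 6 higher and 2 lower of 21. They ranged from the Rieske protein (LOC661125, 0.75 ± 0.13, adjusted p = 0.00133) to NADH dehydrogenase subunit 1 (KEF75_p01, -0.98 ± 0.25, adjusted p = 0.00729). Antioxidant genes had 2 higher and 2 lower of 6, with catalase-like LOC655157 at 0.90 ± 0.14, adjusted p = 0.000799 and peroxiredoxin-6 LOC659242 at -1.53 ± 0.17, adjusted p = 0.000175. Heat shock genes had 6 higher and 4 lower of 13. The small heat shock protein LOC664276 (2.24 ± 0.70, adjusted p = 0.0188) did not pass without control replicate 3 (2.13, adjusted p = 0.0553), nor without that library and fat body replicate 1 together (2.10, adjusted p = 0.0854). Heat shock cognate 71 (LOC100142620) stood at -1.55 ± 0.59, adjusted p = 0.04. It did not pass without control replicate 2 (-1.72, adjusted p = 0.0521) or 3 (-1.15, adjusted p = 0.111). Nor did it pass without tubule replicate 1 (-1.55, adjusted p = 0.055) or 2 (-1.55, adjusted p = 0.0533), or fat body replicate 2 (-1.15, adjusted p = 0.0874) or 3 (-1.35, adjusted p = 0.12). It also did not pass in a fit of the 2 groups alone (-1.57, adjusted p = 0.064) and stood at -2.48, adjusted p = 0.00296 without fat body replicate 1.

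Fatty acid oxidation genes in fat body had 11 higher and 0 lower of 13 (median 0.80; camera adjusted p = 0.0138, adjusted p = 0.887 with an estimated correlation). The most abundant was trifunctional enzyme alpha (LOC662336, 1.15 ± 0.17, adjusted p = 0.000522). The tricarboxylic acid cycle had 10 higher and 2 lower of 18, with aconitase (LOC663732) at 0.87 ± 0.19, adjusted p = 0.00357. Fatty acid and lipid synthesis had 21 higher and 16 lower of 46, with a median of 0.33 against a downward test that did not pass. Fatty acid synthase (LOC662899) fell from 1879 ± 587 CPM to 99.04 ± 58.2 CPM (-4.25 ± 0.45, adjusted p = 0.00013). Glycolysis had 2 higher and 0 lower of 7, ribosomal protein genes 0 higher and 4 lower of 5, proteasome 2 higher and 1 lower of 3, immune genes 5 higher and 4 lower of 12 and apoptosis genes 0 higher and 4 lower of 7. The ubiquitin-ribosomal fusion L40 (LOC656930) stood at -1.17 ± 0.18, adjusted p = 0.000737, lysozyme (Lyz) at -1.14 ± 0.21, adjusted p = 0.00148 and the proteasome subunit LOC663555 at 0.91 ± 0.16, adjusted p = 0.00136.

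Among tissue markers, fat body markers had 8 higher and 6 lower of 15 in fat body. Muscle markers had 22 higher and 10 lower of 38 (median 1.07, mean -0.16; camera adjusted p = 0.0138, adjusted p = 0.887 with an estimated correlation). That call was lost without control replicate 3 and fat body replicate 1 (adjusted p = 0.0508). Paramyosin (LOC659309), a thick filament protein, rose from 2628 ± 127 CPM to 9323 ± 1029 CPM (1.83 ± 0.16, adjusted p = 7.02e-05). Cuticle markers had 20 higher and 3 lower of 40 (median 1.22; camera adjusted p = 0.0116, adjusted p = 0.887 with an estimated correlation). Sensory markers had 10 higher and 28 lower of 48 (median -1.93; camera adjusted p = 0.0138, adjusted p = 0.504 with an estimated correlation). Testis markers had 1 higher and 21 lower of 43 (median -1.54; camera adjusted p = 0.0362, adjusted p = 0.954 with an estimated correlation), a call lost with library totals alone (adjusted p = 0.0632). Control replicate 3 and fat body replicate 1 held the highest testis levels of their groups, as given above. Within the sensory list, chemosensory protein Csp11 stood at 1.12 ± 0.32, adjusted p = 0.0125, and at 1.02, adjusted p = 0.0619 without those 2 libraries. Gut markers had 12 higher and 32 lower of 61 and did not pass as a list (camera adjusted p = 0.0637, adjusted p = 0.887 with an estimated correlation). They passed on ranks (0.0435), with RLE (0.029) and with the authors' size factors (0.0419). Within them, aminopeptidase N-like LOC661831 (-1.04 ± 0.36, adjusted p = 0.0299) stood at -0.45, adjusted p = 0.173 without control replicate 3. It did not pass without fat body replicate 1 (-0.93, adjusted p = 0.0755), 2 (-1.03, adjusted p = 0.067) or 3 (-1.16, adjusted p = 0.0509). Nor did it pass with RLE (-0.83, adjusted p = 0.0577) or the authors' size factors (-0.85, adjusted p = 0.0544). Malpighian tubule markers had 9 higher and 27 lower of 50, nervous system 6 higher and 7 lower of 40, and ovary 1 higher and 0 lower of 3. Vitellogenin receptor (LOC657346) stood at -1.33 ± 0.75, adjusted p = 0.135, and at -2.29, adjusted p = 0.0233 without fat body replicate 1 and -2.60, adjusted p = 0.0186 without that library and control replicate 3. Adjusted over the list alone, counts were as given except for cytochrome P450 (40 higher and 20 lower), ABC transporter (28 higher and 11 lower), carbonic anhydrase (1 higher and 1 lower), heat shock (6 higher and 5 lower), fatty acid oxidation (12 higher and 0 lower), cuticle (19 higher and 3 lower), gut digestive (12 higher and 33 lower) and testis and sperm (1 higher and 13 lower). Median and mean differed in sign for UDP-glucuronosyltransferase, cytochrome c oxidase, other respiratory chain, antioxidant, glycolysis, fatty acid and lipid synthesis, proteasome, immune, muscle and nervous system. Median and test differed in direction for UDP-glucuronosyltransferase, carbonic anhydrase, fatty acid and lipid synthesis and ovary and egg. Medians changed sign with the scaling for UDP-glucuronosyltransferase (-0.047, range -0.30 to 0.14), carbonic anhydrase (-0.005, range -0.26 to 0.20), sulfide metabolism (0.12, range -0.14 to 0.32), cytochrome c oxidase (0.11, range -0.15 to 0.30), other respiratory chain (0.22, range -0.034 to 0.43), glycolysis (0.026, range -0.23 to 0.22) and nervous system (0.080, range -0.18 to 0.29).

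**Figure D3:**
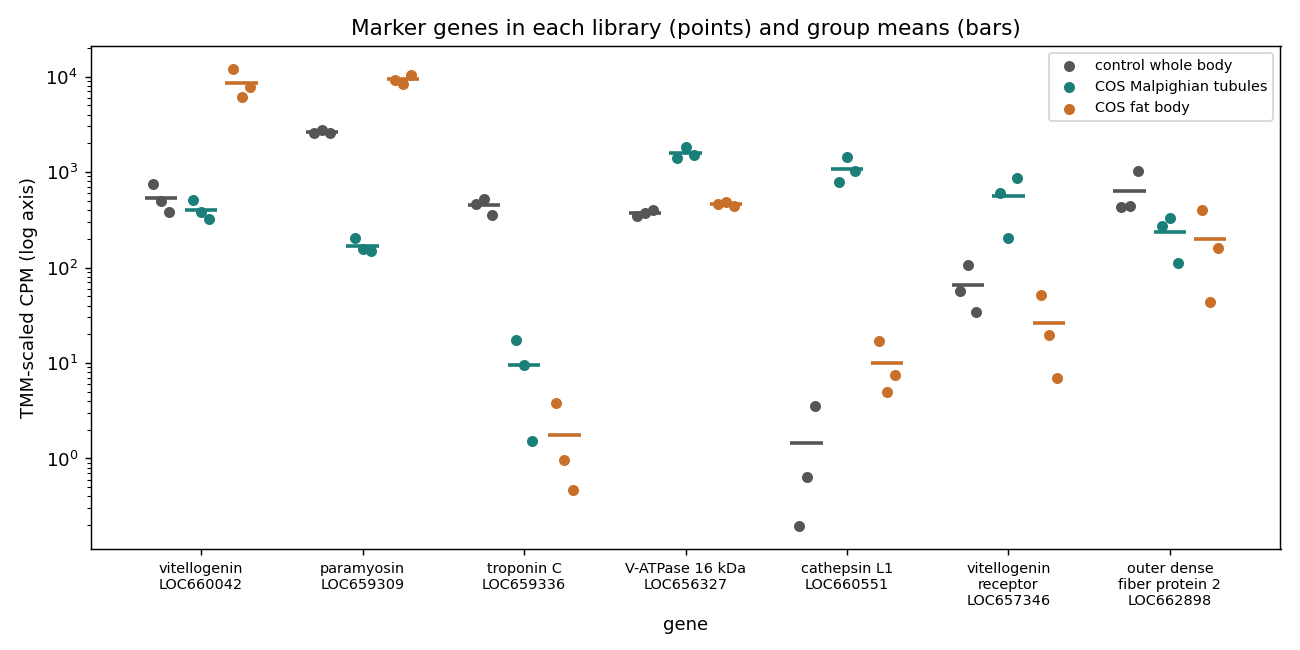
TMM-scaled CPM of 7 marker genes on a log axis, with a point per library and a bar at the mean of each group. Vitellogenin and paramyosin are highest in fat body, the V-ATPase subunit and cathepsin L1 in tubules, and the troponin C LOC659336 in the whole body.

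Between the COS tissues, camera called the muscle, nervous system and cuticle lists higher in fat body than in tubules and the tubule marker and apoptosis lists lower. None of these calls held with an estimated correlation (adjusted p from 0.718 to 0.803). Within the limits on description, mean and overlap, the highest were protein takeout (LOC655472, 7.29 ± 0.38, adjusted p = 6.86e-07, edgeR) and glucose dehydrogenase (LOC662132, 6.65 ± 0.32, adjusted p = 4.15e-07). Within those limits they were followed by venom acid phosphatase (LOC659580, 6.53 ± 0.21, adjusted p = 1.4e-07) and a troponin C (LOC659195, 6.34 ± 0.44, adjusted p = 2.93e-06, 598 ± 34.8 CPM against 7.37 ± 3.73 CPM). Within the same limits the lowest were esterase FE4 (LOC661621, -7.88 ± 0.67, adjusted p = 7.86e-06) and basic proline-rich protein (LOC660391, -7.80 ± 0.54, adjusted p = 2.93e-06). Next were 4-nitrophenylphosphatase (LOC662004, -7.73 ± 0.40, adjusted p = 6.57e-07) and proton-coupled amino acid transporter 4 (LOC664380, -7.67 ± 0.33, adjusted p = 2.56e-07). In all 2077 genes were higher and 2198 lower in fat body (48.6% upward), and 1083 did not pass. With the authors' size factors the majority turned, at 2503 higher and 1959 lower (56.1% upward). RLE gave 2168 higher and 2164 lower, upper-quartile factors 49.7% upward and library totals 47.8%. The groups did not overlap in 80.3% of the genes tested, again a share that the selection favours. The 10% that chance gives holds only for unselected genes.

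Of the lists, muscle had 26 higher and 6 lower of 38 (median 2.70; camera adjusted p = 1.59e-09, adjusted p = 0.718 with an estimated correlation). Nervous system markers had 28 higher and 4 lower of 40 (median 1.49; camera adjusted p = 0.0122, adjusted p = 0.803 with an estimated correlation). Cuticle markers had 20 higher and 6 lower of 40 (median 1.34; camera adjusted p = 0.0307, adjusted p = 0.803 with an estimated correlation). Malpighian tubule markers had 11 higher and 27 lower of 50 (median -1.65; camera adjusted p = 0.0122, adjusted p = 0.803 with an estimated correlation). Apoptosis genes had 0 higher and 7 lower of 7 (median -2.16; camera adjusted p = 0.0399, adjusted p = 0.718 with an estimated correlation). Lists with no camera call included the tricarboxylic acid cycle (13 higher and 0 lower of 18), fatty acid oxidation (12 higher and 1 lower of 13), other respiratory chain (15 higher and 0 lower of 21), gut (14 higher and 41 lower of 61), P450 (40 higher and 25 lower of 74) and ABC transporters (23 higher and 22 lower of 51). The tricarboxylic acid cycle (camera adjusted p = 0.0767) passed on ranks (0.035) and with the authors' size factors (0.0448). Fatty acid oxidation (adjusted p = 0.0782) passed on ranks (0.035), with the authors' size factors (0.0448) and without control replicate 3 and fat body replicate 1 (0.0472). The gut list (adjusted p = 0.103) passed with the authors' size factors (0.0448). Fatty acid synthase (LOC662899) had -0.85 ± 0.40, adjusted p = 0.0723 between the tissues, -0.87, adjusted p = 0.0415 without control replicate 3, -1.42, adjusted p = 0.00303 without fat body replicate 1 and -1.42, adjusted p = 0.0014 without both. The proteasome subunit LOC663555 (0.47 ± 0.16, adjusted p = 0.0236) did not pass without tubule replicate 2 (0.40, adjusted p = 0.0607) or fat body replicate 3 (0.35, adjusted p = 0.0906), nor in a fit of the 2 groups alone (0.48, adjusted p = 0.0576). Adjusted over the list alone, counts were as given except for cytochrome P450 (41 higher and 25 lower), proteasome (0 higher and 0 lower), fat body (7 higher and 1 lower), cuticle (20 higher and 4 lower) and testis and sperm (2 higher and 10 lower). Median and mean differed in sign for UDP-glucuronosyltransferase, esterase and cytochrome c oxidase. Median and test differed in direction for heat shock and proteasome. Medians changed sign with the scaling for ABC transporter (-0.61, range -0.63 to 0.013), heat shock (-0.17, range -0.19 to 0.49), proteasome (-0.22, range -0.25 to 0.45) and testis and sperm (-0.51, range -0.53 to 0.12).

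Genes changed in the same direction in both tissues numbered 647, with 375 higher and 272 lower, where independent lists would share 563 and 598. Opposite directions held 826 genes higher in tubules and lower in fat body and 735 the other way, where independent lists would share 645 and 522. Since the selection of genes on the contrast between the tissues favours opposite directions, independent lists are no valid reference here. In 40 simulations of unchanged groups against shared controls at most 1 gene was shared. The same-direction split was 58.0% upward with TMM, but 236 higher and 495 lower (32.3% upward) with the authors' size factors, 230 and 496 (31.7%) with library totals alone, and 253 and 416 (37.8%) with upper-quartile factors. Across genes, which are not independent replicates, the 2 sets of log2 fold changes correlated at -0.0962 (0.505 simulated), with a covariance of -0.265 (0.0838 simulated). The simulated data held neither changed genes nor the selection, so the distance between these values decides nothing. The 3 controls cannot be split into parts of 2, so part of any shared change may come from the shared controls.

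Within the same limits on description, mean and overlap, the leading genes higher in both tissues were the multidrug resistance-associated proteins LOC656937 (4.23 ± 0.47 in tubules, 3.41 ± 0.45 in fat body) and LOC657102 (4.15 ± 0.26 and 2.63 ± 0.25). With them were synaptic vesicle glycoprotein 2B (LOC661311, a transporter family member, 2.67 ± 0.34 and 3.55 ± 0.35) and cathepsin L1 (LOC660551, 2.76 ± 0.82 in fat body). Cathepsin L1 stood at 0.194, 0.633 and 3.51 CPM in controls and 17.2, 4.94 and 7.56 in fat body. Its fat body change was 2.37, adjusted p = 0.0546 without control replicate 2 and 4.55, adjusted p = 0.00131 without control replicate 3. Together, the 12 listed cathepsin L and zingipain genes were not higher in fat body, at 2569 ± 225 CPM against 3144 ± 374 CPM in the whole body. In tubules they summed to 7468 ± 1509 CPM. Within those limits the leading genes lower in both were LOC103313838, Csp13 (-6.70 ± 0.95, adjusted p = 0.00047 in fat body), LOC660329 and the troponin C LOC659336 (-5.56 ± 0.93, adjusted p = 0.000778 in tubules).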

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

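Of the tests reported here, the splits and regroupings of the libraries were chosen before their results were seen, and the tests of muscle, gut, ovary, carry-over, scaling and missing tissues were chosen after. The limits of the gut and muscle tests were set after the values were seen, and the muscle limit of at least 3 genes was met by exactly 3. For cathepsin L1 the bound was also changed after a first result near its limit. The scaling test of the 4 genes higher in both tissues was set aside after its result was seen.

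Results were picked out here because the direct test of fat body against tubules passed, so that the effects against the shared control differed between the tissues. Genes that passed in opposite directions in the tissues and also between them numbered 1561, from a table whose selection favours such genes. By list, median log2 of fat body over tubules was 2.70 for muscle, 1.49 for nervous system, 1.34 for cuticle, -1.65 for Malpighian tubule and -2.16 for apoptosis. With an estimated correlation none of these 5 lists passed by camera (adjusted p from 0.718 to 0.803). Of the named genes, the log2 fold change of fat body over tubules was above 0 for LOC655472 7.29, LOC662132 6.65, LOC659580 6.53, LOC662300 6.39, LOC659195 6.34, LOC103312153 6.27, LOC658599 6.04, LOC659309 5.78, LOC655392 4.99, Csp11 4.88, LOC659136 4.81, LOC660042 4.41, LOC661102 4.37, LOC657196 4.29, LOC662608 3.73, LOC660270 3.45, LOC660739 2.47, LOC656954 2.21, LOC656825 2.16, LOC659585 2.10, LOC660846 2.05, LOC663732 1.93, LOC656282 1.73, LOC655751 1.58, LOC662336 1.29, KEF75_p12 1.04, LOC655157 0.99, LOC661246 0.95, KEF75_p11 0.93, LOC661311 0.88, LOC103313429 0.83, LOC661125 0.74 and LOC663555 0.47. It was below 0 for LOC661621 -7.88, LOC660391 -7.80, LOC662004 -7.73, LOC664380 -7.67, LOC660481 -7.54, LOC107397713 -7.52, LOC658343 -7.44, LOC103313304 -6.95, LOC658760 -6.90, LOC660551 -6.77, LOC107399265 -6.21, LOC658506 -5.43, LOC657346 -4.41, LOC655958 -4.34, LOC660329 -3.76, LOC657602 -3.61, LOC657021 -2.97, LOC656279 -2.91, LOC664276 -2.83, LOC661391 -2.53, LOC659336 -2.45, LOC661831 -2.25, Lyz -2.15, LOC655619 -1.99, LOC659242 -1.84, LOC656327 -1.77, LOC663941 -1.63, LOC657102 -1.52, LOC658563 -1.26 and LOC656930 -1.24.

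Muscle genes against the whole body had 22 higher and 10 lower of 38 in fat body and 3 higher and 30 lower of 38 in tubules. The fat body call of the list was lost with an estimated correlation (adjusted p = 0.887) and without control replicate 3 and fat body replicate 1 (adjusted p = 0.0508), and the tubule call with an estimated correlation (adjusted p = 0.421). The 5 scalings decide nothing about scaling here, though the lowest list median was 0.807, with 20 members higher and 11 lower. They moved log2 fold changes of fat body over control by -0.26 to 0.20 against TMM, too little to undo a TMM median of 1.07. Of the 21 muscle genes at 200 CPM or more, 3 fell in fat body. They were flightin (LOC657758, -2.59 ± 0.52, adjusted p = 0.00239, edgeR), troponin C (LOC659336, -8.01 ± 1.06, adjusted p = 0.000351) and actin (LOC655409, -4.04 ± 0.33, adjusted p = 5.62e-05). The first of these is a flight muscle protein. The 3 argue against muscle of every kind carried along with unchanged transcripts. A fall of the 3 with treatment is not excluded, since the fat body was treated and the whole body was not. Muscle other than flight muscle carried along may account for the 15 of 21 that rose, by 0.68 to 2.34, and cannot be told apart from a change with treatment or with tissue, because the design joins them.

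In tubules the gut list had 21 higher and 13 lower of 61 and the ovary and egg list 3 higher and 0 lower of 3. Neither passed as a list (camera adjusted p = 0.423 for each). In fat body over tubules the ovary and egg list had 1 higher and 2 lower of 3, so its members did not move together. Gut tissue carried along may be a source, since 16 of the 20 gut genes most abundant in the whole body lay above it, with 8 passing upward and 3 downward, but the limit of the test was set after these values were seen, the count was 13 under another scaling, and tubules may express these genes themselves. Ovary tissue carried along may be another, since bicaudal C (LOC663844) ranked 2 of 5357 genes in how closely its deviations within groups followed vitellogenin receptor, with 270.2, 85.1, 378 CPM in the tubule libraries beside 604, 202 and 857. Both were noticed first and tested on the same values, so neither can be told apart from expression in tubules or a response to treatment.

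For the 4 genes named as higher in both tissues, the 5 scalings decide nothing about scaling, though all 4 passed under each. The genes were picked for the largest changes (at least 2.63 with TMM), and the scalings moved log2 fold changes against control by at most 0.49, so no scaling tried was able to undo them. Tubule RNA in the fat body libraries is argued against for LOC656937, LOC657102 and LOC661311, which would need at least 29.1% tubule RNA (19.8% from extreme libraries) where the gene with the smallest fat body to tubule ratio (LOC655193) allows 0.125% even from extreme libraries. Cathepsin L1 would need 0.784%, against 0.064% from means, yet its extreme libraries need only 0.0999%, so carry-over may account for it and cannot be excluded. Tissues in the whole body that lack these transcripts cannot be told apart from a response to COS. Each of the 3 other genes sets an upper bound on the fat body share of whole-body RNA, the smallest being 8.56%. That lay above the upper bound of 6.28% set by vitellogenin. Both bounds divide untreated whole-body levels by treated fat body levels, so they hold only if COS left these genes unchanged. Cathepsin L1 sets an upper bound of 0.134% on the tubule share of whole-body RNA, from a whole-body mean of 1.45 CPM. That bound holds on the same condition, and the tubule share itself was not measured. Treated whole bodies and untreated tissues are not analysed here, so a response to COS stays open and untested.

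The 6 libraries of each comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 3522 genes for tubules over control, 3697 for fat body over control and 4029 for fat body over tubules (1 of 10 splits each), and the highest other split gave 0 by edgeR, with at most 83, 53 and 285 genes at an unadjusted p under 0.05. The listed genes had been selected on the real grouping, and each other split mixes the 2 groups. The distance between the real and the other gene counts was thus largely fixed in advance and is no evidence. For gene lists the real splits gave 7, 6 and 5 calls and the highest other splits 14, 7 and 9, and 8, 4 and 8 of the 10 splits gave as many. Of 100 regroupings of the 9 libraries, 6 gave as many genes changed in the same direction in both tissues (647, highest other 2141), so these regroupings did not exclude chance. The 5 others each placed 1 whole group of the study where the controls stood, which points to the structure of the samples.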

How the results depend on the processing

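The authors' size factors, library totals alone, lists as first written and the fit without control replicate 3 and fat body replicate 1 were chosen after the data were examined. Counts of genes stayed within 1.5 times under each setting, with an exception. With an absolute log2 fold change of at least 1, a stricter rule by construction, 325 genes changed in the same direction in both tissues. Stable counts did not mean the same genes. Of the 647 same-direction genes with TMM, 439 stayed with the authors' size factors, 502 with library totals, 525 with upper-quartile factors and 571 with RLE. Leaving out 1 library at a time gave 3023 to 3583 genes for tubules over control, 3004 to 3869 for fat body over control, 4029 to 4533 for fat body over tubules and 475 to 755 in both tissues. Without control replicate 3 and fat body replicate 1 together the counts were 3261, 3521, 4569 and 522. With an estimated correlation camera called 0, 0 and 0 lists in the 3 comparisons (2, 1 and 0 at an unadjusted p under 0.05). On ranks it called 7, 8 and 7, and with the authors' size factors 8 for fat body over tubules. For the sensory list in fat body over control the estimated correlation was 0.0053, below the preset 0.01, yet camera gave adjusted p = 0.504. A higher correlation among its own members thus does not account for that loss. The other lists called at the preset had estimates above 0.01, and the cause of the lost calls was not tested. The replicate numbers showed no sign of pairing the samples. Deviations of same-numbered libraries correlated from -0.463 to 0.385, and those of differently numbered libraries from -0.551 to 0.459. With 3 libraries per group this cannot exclude pairing. With the number as a block the counts were 3151, 3467, 4129 and 556 genes and 7, 8 and 7 lists. Camera calls gained there were fat body markers in tubules (adjusted p = 0.0106) and gut in fat body over control (0.0153). Between the tissues they were fat body markers (0.0332) and gut (0.0356). Fatty acid synthase (LOC662899) also passed between the tissues with the block (-0.96, adjusted p = 0.0498, edgeR). The pseudocount alternative was not run because the table holds counts.

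No list that passed the test reversed. Among lists that did not pass, the direction of the test reversed, with these adjusted p: in tubules over control, cytochrome c oxidase (on ranks 0.98, upper quartile 0.983, authors' factors 0.934, totals 0.962, without the 2 libraries 0.996) and glutathione S-transferase (block 0.896, RLE 0.971). In fat body over control these were lipid synthesis (ranks 0.806), antioxidant (upper quartile 0.998, totals 0.987), and, without the 2 libraries, carbonic anhydrase 0.972 and ovary 0.972. In fat body over tubules they were ABC transporters (ranks 0.978, without the 2 libraries 0.999) and esterase (lists as first written 0.956). Of named genes, log2 reversed for LOC656930 in tubules (authors' factors -0.41, totals -0.16, upper quartile -0.15, with 1 library left out -0.016 to 0.15), LOC663555 in tubules (authors' factors -0.044), LOC103313429 in fat body (totals -0.14, upper quartile -0.013) and LOC662898 between tissues (authors' factors 0.37, with 1 library left out -1.22 to 0.23); the cause was not tested. Depth limits genes of few counts, such as LOC662300 with 5 counts in tubules and LOC658506 with 4 in fat body.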

Other observations

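The genes below were chosen after their values were seen. Of the muscle list, 10 of 38 members fell in fat body, troponin C (LOC659336), muscle actin (LOC655409) and flightin (LOC657758) among them. Other members were highest there, and myosin heavy chain (LOC659358) stood at 2930.2 ± 29.4 CPM in the whole body, 227 ± 25.8 CPM in tubules and 8421 ± 1309.5 CPM in fat body, and twitchin (LOC660154) at 825 ± 21.01 CPM, 104 ± 12.3 CPM and 3897 ± 693 CPM. Hexamerins, which store amino acids, went both ways in fat body. Hexamerin 1B (HEX1B) stood lower in both tissues (-3.32 ± 0.42, adjusted p = 0.000146 in tubules and -2.46 ± 0.40, adjusted p = 0.000894 in fat body, edgeR), and so did hexamerin 2 (HEX2, -2.08 ± 0.50, adjusted p = 0.00544 and -2.03 ± 0.50, adjusted p = 0.00647), while hexamerin 5 (HEX5) rose in fat body (1.05 ± 0.20, adjusted p = 0.00197). A second vitellogenin (LOC658755) rose in fat body by 2.34 ± 0.46, adjusted p = 0.00217. Of the lipid droplet surface proteins, LOC660518 rose in both tissues (1.92 ± 0.37, adjusted p = 0.00164 and 1.56 ± 0.36, adjusted p = 0.00525) while LOC659061 rose in fat body and fell in tubules (1.31 ± 0.25, adjusted p = 0.00195 and -2.59 ± 0.26, adjusted p = 4.41e-05, with 3.90 ± 0.28, adjusted p = 3.21e-06 between the tissues).

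Of the apoptosis list, 2 caspases are given here. Caspase-1 (LOC655845) had 78.6 ± 4.78 CPM in tubules and 17.5 ± 3.18 CPM in fat body (-2.16 ± 0.18, adjusted p = 6.65e-06, edgeR), and caspase Dronc (LOC100142149), an initiator caspase, 67.02 ± 18.7 CPM and 15.8 ± 2.67 CPM (-2.09 ± 0.26, adjusted p = 5.91e-05). Cytochrome P450 CYP4G7 (Cyp4g7), of a family that makes cuticular hydrocarbons, stood lower in both tissues than in the whole body (-2.69 ± 0.35, adjusted p = 0.000191 in tubules and -4.004 ± 0.38, adjusted p = 8.47e-05 in fat body). The 12 listed cathepsin L and zingipain genes summed to 3144 ± 374 CPM in the whole body, 7468 ± 1509 CPM in tubules and 2569 ± 225 CPM in fat body. This sum does not depend on how reads were split among these 12. Any reads shared with genes outside the 12 would still affect it.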
